A study of Homo sapiens with 6 samples.

How the data were processed

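RNA was measured in 6 libraries of HepG2 cells, 3 from cells given 20 µM atractylon and 3 from untreated cells. Per the labels' protocols, RNA was taken with a SMART-Seq v4 low-input kit, had an integrity number above a set minimum, and was made into Illumina libraries. Groups and replicate numbers were taken from the sample titles.

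The authors deposited a table of 180253 transcripts with 2 values per library, an expected count and an FPKM value, per the file headers. An expected count is an estimated number of reads per transcript that need not be whole, since reads shared between transcripts are divided. FPKM is the expected count scaled by the reads assigned in the library and by a length. The deposited FPKM values imply an effective length, shorter than the transcript by a median of 258.5 to 269.0 bases per library, which raises the FPKM of short transcripts and their chance of passing the FPKM filter. The table also gave a transcript length. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1, DESeq2 1.6.3 and the genome build hg19 were used, with no role or order given. The program that made the expected counts, the transcript annotation and the use of strand are not given in the sources used here. Low-input amplification can favour some transcripts by GC content and length, and dividing reads between transcripts makes the values of overlapping genes, readthrough genes and near-identical copies uncertain.

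Transcripts were matched by identifier to genes of GENCODE 29, which is built on GRCh38. The annotation was used for names and gene classes, and no coordinates are given because the build differs. Of the transcripts, 153245 (85.0%) matched, and the 27008 that did not held 8.70% to 9.07% of the counts per library. They were left out of library sizes and tests. Expected counts and FPKM values were summed over the transcripts of each of 33791 genes, of which 514 were lncRNA genes of GENCODE 29. The summed expected counts were rounded to whole numbers. Total expected counts per library ranged from 5859575 to 8832092, and the 10 most abundant genes took 6.98% to 7.58% of gene counts. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom between 3.43 and 19.61, so no pair looked like repeat copies of 1 library. This does not show that they came from separate cultures.

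Genes with an FPKM of at least 0.5 in at least 3 of the 6 libraries were tested, 12302 in all, of which 11757 were protein-coding, 438 pseudogenes and 105 lncRNAs. Before the data were examined, a limma test on log2 FPKM had been chosen, to be replaced by a count test if the table held counts. It held expected counts, so edgeR 4.0.16 was used, with trimmed-mean scaling, glmQLFit and glmQLFTest, group as the only term, 2-sided, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. Standard errors were derived from the quasi-likelihood statistic. Values are given as CPM, which are counts scaled to the effective size of the library, with the SD over 3 libraries. Fold changes from limma were on the log2(FPKM + 0.5) scale, which understates the change of low genes.

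The rule for named genes was fixed before the data were examined. It took genes that were not lncRNAs, and lncRNAs, that passed the threshold with an official symbol, an FPKM minimum and no overlap between groups. Where fewer passed it took up to 5 per direction with the smallest p. It added TMPO-AS1, CCDC183-AS1 and their sense neighbours, and up to 4 members with the smallest p of each list that passed or that bears on invasion and migration. Genes named outside the rule are marked as chosen after their values were seen, with these exceptions. ZNF516 and FAAP100 are named because they passed the threshold in a refit. LINC01554, DLEU1, SNHG4 and SNHG20 are named as examples of their lists, which no rule picked. Some genes are not reported here by name, including 1 that the rule took.

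Gene lists were also fixed before the data were examined. Of 40 lists, 38 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The 2 lists below that minimum were fibroblast and stromal markers, with 2 tested members, and lncRNAs known from cancer, with 3. The lists were tested again with an estimated correlation and with fry, which tests whether a set's genes move one way and does not compare them with other genes. The use of log2 CPM in place of log2 FPKM for the lists, and of CPM to judge overlap, was decided after the table was seen to hold counts.

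The tests were checked on simulated counts with the means, library sizes and spread of these libraries and 200 genes changed by known folds. Over 12302 genes in the simulated comparison of atractylon with control, edgeR recovered 86.4% of genes changed 4-fold, 68.7% of those changed 2-fold and 16.4% of those changed 1.5-fold. In the same simulation edgeR also called 9 unchanged genes. With no gene changed, it called 0 genes and camera called 0 lists. The list tests were also run on 20 draws with a shift of 0.15 given to the cholesterol list and 20 with a shift of -0.2 given to the mitochondrial list. The test with an estimated correlation called the shifted list in 0 draws of either kind. Failing that test therefore does not by itself argue against a list. These simulations drew genes independently, so they do not measure the effect of correlated genes on the list tests.

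Alternatives set before the data were examined covered pseudocounts, filters on low values, scaling, moderation, the replicate number as a block, the list tests and each replicate left out in turn. Those on pseudocount, TPM and quantile scaling and trend were run with limma 3.58.1 on log2 FPKM, so they changed the test as well. Alternatives added after seeing the data were DESeq2 1.42.0, limma on log2 CPM, unmatched transcripts kept, the first replicate of both groups left out, and removal of smooth trends with GC content, with length or with both. Trends were fitted per library by lowess (span 0.3) on the deviation of log2 CPM from the mean over libraries and entered as offsets in edgeR. GC content came from the GENCODE 29 transcript sequences and was known for 12301 of the 12302 genes. Intervals and floors cover counting error only where they come from counts alone, and the floor was 3 counts over a group. R 4.3.3 and Python 3.11.15 were used.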

Results

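The response of HepG2 cells to atractylon was measured by RNA sequencing. HepG2 is a human liver cancer line, and atractylon is a sesquiterpenoid found in the essential oil of Atractylodes rhizomes. The series held 6 libraries, 3 from cells given 20 µM atractylon and 3 from untreated cells. Its stated purpose was to find long non-coding RNAs (lncRNAs) that differ with treatment, in relation to invasion and migration. The values were expected counts per transcript, summed here per gene. Totals were 8072321, 7490941 and 7394281 expected counts in atractylon replicates 1 to 3, and 5859575, 7268968 and 8832092 in control replicates 1 to 3. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

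The first comparison asked which genes differed between treated and untreated cells. No single gene passed the threshold between treated and untreated cells. Of 12302 genes tested, 0 were higher and 0 were lower at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 there were 196 genes, 97 with higher and 99 with lower values, against 615 expected by chance. DESeq2 and limma also called 0 genes, with 102 and 401 genes at an unadjusted p below 0.05. The 2 groups did not overlap in 704 genes (5.7%), against 10% by chance for 3 libraries against 3.

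The genes with the smallest p included the following, and none of them passed the threshold (adjusted p = 0.9999 by edgeR for each, n = 3 per group). Higher values with atractylon were seen for the liver fatty acid-binding protein FABP1, at 70.3 ± 4.98 CPM (SD) against 50.9 ± 3.51 CPM. The same direction was seen in low-abundance genes: CNTNAP3 at 2.29 ± 0.777 against 0.509 ± 0.122 CPM (2.80-fold on FPKM, against 4.50-fold on CPM), JRKL at 3.01 ± 1.53 against 0.363 ± 0.478 CPM, and the Notch ligand DLL3 at 3.51 ± 1.18 against 1.36 ± 0.116 CPM. Lower values were seen for IKBKE, a kinase of innate immune signalling, at 4.53 ± 0.940 against 10.1 ± 0.274 CPM, with a log2 fold change of -1.16 by edgeR and -0.508 by limma on log2 FPKM. LARS, the cytosolic leucyl-tRNA synthetase, was at 16.7 ± 4.37 against 29.1 ± 3.07 CPM, and TTC19, an assembly factor of respiratory complex III, at 2.93 ± 1.02 against 7.12 ± 1.66 CPM. ANKHD1-EIF4EBP3 was at 13.9 ± 4.81 against 29.4 ± 2.76 CPM. It is a readthrough gene that shares its sequence with its neighbours, so its value is uncertain. NEK3 had 0 counts in the treated libraries and 22 in the control libraries. Its pooled control value was 7.54-fold above a floor of 3 counts over the treated group. The error of the 22 control counts is not in this ratio, so it is no lower limit of the change.

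The precision bounded how large an undetected change of a gene could have been. The median standard error of a log2 fold change was 0.196. The 95% confidence interval of the change lay within 2-fold in either direction for 9996 genes (81.3%), and within 1.5-fold for 6723 genes (54.6%). In counts simulated with the spread of these libraries, the same test over 12302 genes recovered 68.7% of genes changed 2-fold and 16.4% of genes changed 1.5-fold.

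**Figure D1:**
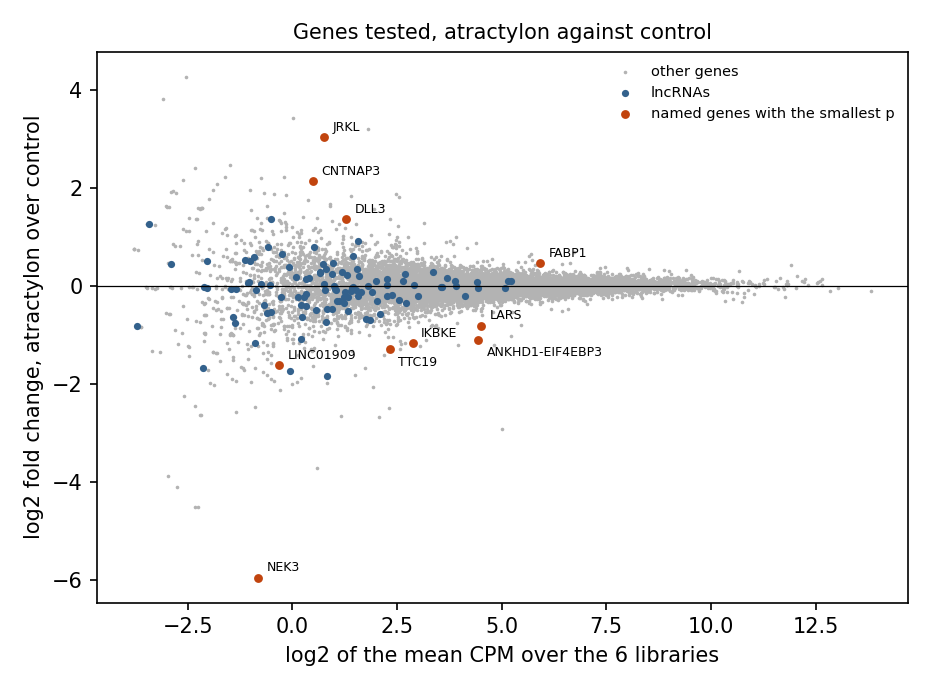
Log2 fold change of each of the 12302 genes tested (atractylon over control, vertical axis) against the log2 of its mean CPM over the 6 libraries (horizontal axis). Grey points are genes, blue points the 105 lncRNAs, and red points the genes named in the text among those with the smallest p whose groups did not overlap, none of which passed the threshold. The widest fold changes lie among genes of low abundance.

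The second comparison addressed the lncRNAs, which were the stated target of the study. LINC01909 was the one lncRNA with an official symbol and no overlap between the groups that had an unadjusted p below 0.05, at 0.379 ± 0.200 CPM in treated and 1.23 ± 0.365 CPM in untreated cells (log2 fold change -1.61 ± 0.61, SE, n = 3 per group). It did not pass the threshold, with an edgeR adjusted p of 0.9999 over all genes and 0.9991 over the lncRNAs alone. Of 105 lncRNAs tested, 0 were higher and 0 were lower by edgeR, also when adjusted over the lncRNAs alone. At an unadjusted p below 0.05 there were 3, and DESeq2 and limma also called 0. The other 2 of these 3, chosen after their values were seen, were AL020996.1 at 0.443 ± 0.410 against 1.48 ± 0.126 CPM and AC008537.4 at 3.89 ± 0.764 against 2.04 ± 0.976 CPM.

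Of 77 lncRNAs known from cancer, 3 had a transcript matched by identifier, LINC01554 and DLEU1 among them. All 3 were tested, too few for a test of that list, and the others could not be analysed here. The genes that host small nucleolar RNAs formed a list of 5 tested members, including SNHG4 at 2.72 ± 1.35 against 2.70 ± 0.957 CPM and SNHG20 at 1.99 ± 1.13 against 2.03 ± 0.499 CPM. Of these 5 members 2 had positive and 3 negative fold changes, 0 passed the threshold adjusted over the list alone or over all genes, and the list had a camera adjusted p of 0.835. Depth limited this comparison: the median lncRNA had 1.93 CPM, 30 of the 105 lay below 1 CPM, and the 95% interval lay within 2-fold for 30 of the 105 (28.6%). Of the 16054 lncRNA genes of the annotation, 514 had a transcript matched by identifier, and any lncRNAs among the unmatched transcripts were not analysed here.

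The antisense RNAs TMPO-AS1 and CCDC183-AS1, which are associated with the study, were not analysed here. Their sense neighbours were tested. TMPO, which encodes a nuclear lamina protein, was at 63.7 ± 11.6 CPM in treated and 65.7 ± 4.89 CPM in untreated cells. CCDC183 was at 14.7 ± 4.49 against 16.9 ± 1.02 CPM. Neither passed the threshold (edgeR adjusted p = 0.9999 for both, n = 3 per group), and whether the counting used strand is not stated, so reads of an antisense partner cannot be told apart from theirs.

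The third comparison asked whether groups of genes moved together. Of 38 lists tested with camera at a preset correlation, 1 was higher and 1 was lower with atractylon. The genes of cholesterol synthesis and its regulator SREBP2 were higher as a group: 26 of 29 tested members had positive fold changes, with a mean log2 fold change of 0.143 and a median of 0.157 (adjusted p = 2.13e-08). Without atractylon replicate 1 the mean was 0.0866 (adjusted p = 0.00255). The call was lost with other tests of the same list, with an adjusted p = 0.0882 with an estimated correlation and 0.443 by fry. Those tests had little power at this size: in 20 simulated draws with independent genes, a shift of 0.15 given to this list was called 17 times at the preset correlation, 0 times with an estimated correlation and 5 times by fry. The members with the smallest p included enzymes of the pathway. DHCR7, which catalyses the last step to cholesterol, was at 524 ± 34.4 against 415 ± 22.2 CPM (log2 fold change 0.33 ± 0.10, SE, n = 3 per group). The lanosterol synthase LSS was at 570 ± 57.3 against 460 ± 19 CPM, and the mevalonate decarboxylase MVD at 177 ± 23.5 against 144 ± 6.78 CPM. HMGCS1, which acts early in the pathway and was chosen after its values were seen, had a log2 fold change of 0.03 ± 0.20 (SE). No member passed the threshold over all genes, and 0 passed when adjusted over the list alone.

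Transcripts encoded by the mitochondrial genome were lower as a group. All 13 tested members had negative fold changes, with a mean log2 fold change of -0.23 and a median of -0.22 (camera adjusted p = 1.12e-09). This call was also lost in the other tests, with an adjusted p = 0.731 with an estimated correlation and 0.677 by fry. A shift of -0.2 given to this list in 20 simulated draws with independent genes was called 19 times at the preset correlation. It was called 0 times with an estimated correlation and 7 times by fry. The members of this list were not independent, so these draws do not measure how the tests perform on it. The complex I subunit MT-ND4L was at 72.1 ± 9.81 against 102 ± 20.3 CPM, and the ATP synthase subunit MT-ATP6 at 1538 ± 157 against 1912 ± 151 CPM. MT-ND2 was at 1333 ± 169 against 1607 ± 132 CPM and MT-ND3 at 300.1 ± 27.7 against 352.5 ± 35.3 CPM. The 13 members were strongly correlated between libraries (estimated correlation 0.524), and 0 of them passed the threshold over all genes or adjusted over the list alone. Mitochondrial genes took 2.68%, 2.73% and 3.16% of gene counts in the treated libraries and 3.11%, 3.06% and 3.54% in the untreated ones. Nuclear-encoded subunits of the respiratory chain had a mean log2 fold change of 0.01 over 68 members and a camera adjusted p of 0.835. In 3 of 26 refits that list passed, 2 times higher and 1 time lower, and in 0 with an estimated correlation (adjusted p of at least 0.691).

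**Figure D2:**
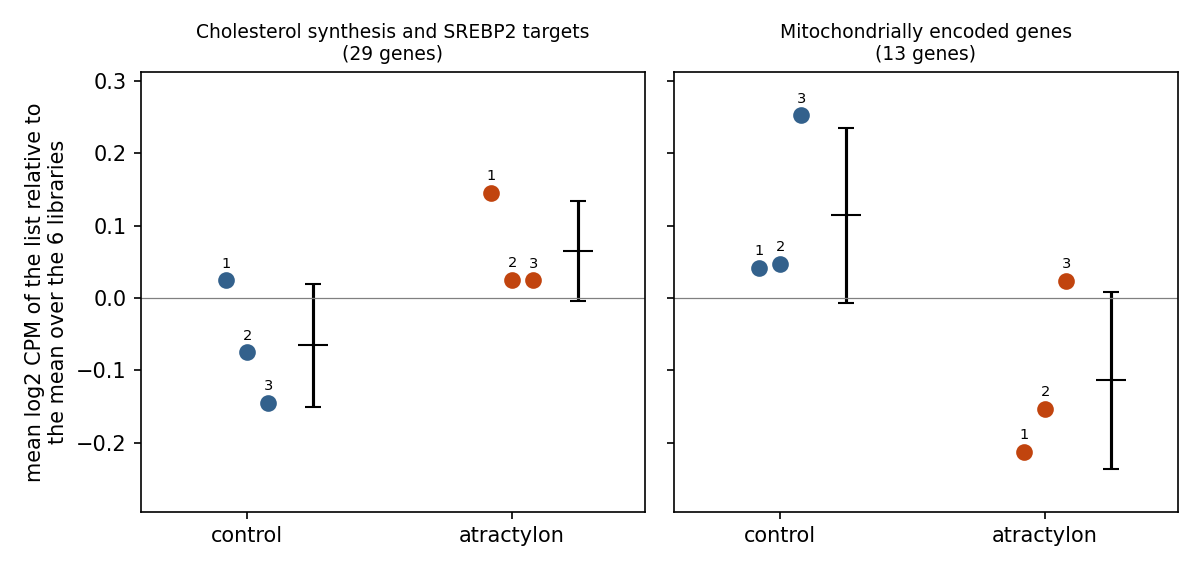
Mean log2 CPM of the 29 cholesterol genes and of the 13 mitochondrial genes in each library, relative to the mean over the 6 libraries (vertical axis), by group (horizontal axis). Points are libraries with their replicate numbers, and bars give the mean and SD of 3 libraries. For the cholesterol genes 2 of the 3 treated libraries lie above every control, 1 of them barely (0.0255 against 0.0246). For the mitochondrial genes all 3 lie below every control, atractylon replicate 3 by little (0.0237 against 0.0419 in control replicate 1).

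The lists that answer the question of invasion and migration did not pass the threshold with all 6 libraries as counted, and 2 of them passed in some refits. Among EMT and mesenchymal markers, 5 of 17 tested members had positive and 12 negative fold changes (camera adjusted p = 0.425). The YAP target CYR61 was at 14.3 ± 0.730 against 18.7 ± 0.533 CPM and SPARC at 138 ± 8.46 against 152 ± 8.12 CPM. LOX, which crosslinks collagen, was at 11.6 ± 1.27 against 8.45 ± 1.00 CPM, and the integrin ITGA5 at 5.59 ± 0.946 against 3.61 ± 0.858 CPM. On FPKM the ITGA5 difference was 1.03-fold, against 1.55-fold on CPM. Among matrix proteases and their inhibitors, 16 of 23 members had positive fold changes (adjusted p = 0.148). This list was higher in 2 of 26 refits, with a filter at FPKM 1 (adjusted p = 0.0201, or 0.628 with an estimated correlation) and without control replicate 3 (0.0339, or 0.691). Its members included TIMP1 at 50.6 ± 5.51 against 40.4 ± 3.22 CPM, PLAU at 27.3 ± 1.49 against 22.6 ± 2.77 CPM, MMP15 at 371 ± 34.5 against 332 ± 19 CPM and TIMP2 at 148 ± 6.63 against 136 ± 14.2 CPM. Epithelial junction and keratin genes had 10 positive and 17 negative fold changes among 27 members (adjusted p = 0.425), with OCLN at 9.20 ± 4.32 against 12.7 ± 2.07 CPM and CLDN1 at 47.0 ± 5.80 against 54.0 ± 6.29 CPM. PKP2 was at 31.2 ± 6.55 against 34.8 ± 0.706 CPM and DSG2 at 49.0 ± 21.2 against 42.3 ± 4.85 CPM. Cell migration and focal adhesion genes had 24 positive and 16 negative fold changes among 40 members (adjusted p = 0.974), including ZYX at 189 ± 20.3 against 159 ± 25.5 CPM, BCAR1 at 240 ± 20.3 against 210 ± 15.9 CPM and PTK2 at 46.6 ± 4.06 against 53.6 ± 2.88 CPM. YAP and TEAD targets (adjusted p = 0.425) did not pass. TGF-beta and SMAD targets, with 14 of 20 members at negative fold changes, did not pass as counted (adjusted p = 0.148) and were lower in 4 of 26 refits. These were the removal of the GC trend (adjusted p = 0.0249, or 0.464 with an estimated correlation), the removal of GC and length trends (0.0161, or 0.396), and the fits without atractylon replicate 3 (0.0442, or 0.822) and without control replicate 1 (0.0386, or 0.687). In these lists 0 members passed the threshold, over all genes or adjusted over the list alone.

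The remaining lists did not pass the threshold at the preset correlation. Nearest to it were the genes of the endoplasmic reticulum unfolded protein response, with 22 of 28 members at negative fold changes (adjusted p = 0.0599). Genes of bile acid and cholesterol disposal had 13 of 17 members at positive fold changes (adjusted p = 0.0599), and genes of fatty acid and triglyceride synthesis 16 of 24 (adjusted p = 0.0741). Over the 26 refits these 3 lists passed in 7 (lower), 8 (higher) and 11 (higher), the last including each of the 7 fits on log2 FPKM. Of those fits, limma without trend and with robust moderation gave camera the same values as limma on log2(FPKM + 0.5), so they repeated its result. With an estimated correlation none of the 3 passed in any refit, at adjusted p of at least 0.491, 0.322 and 0.207. Proliferation genes had negative medians, with adjusted p of 0.148 for G2/M and mitosis genes and 0.238 for DNA replication and G1/S genes. G2/M and mitosis genes were lower in 1 of 26 refits, without control replicate 2 (adjusted p = 0.0293, or 0.765 with an estimated correlation). Lists that passed in refits in both directions were cytosolic ribosomal proteins, 3 times higher and 2 times lower, and replication-dependent histones, 2 times higher and 2 times lower. Glycolysis genes were higher in 2 refits, and none of these lists passed with an estimated correlation. The p53 targets, NRF2 antioxidant targets and integrated stress response targets each had an adjusted p of 0.425. Hepatocyte secreted proteins and identity genes (46 members, adjusted p = 0.996) and cytochrome P450 and xenobiotic enzymes (32 members, adjusted p = 0.835) did not pass. Markers of other cell types were sparse: blood and immune markers had 6 tested members, biliary markers 7 and endothelial markers 5, with adjusted p of 0.592, 0.992 and 0.592.

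Libraries also differed in a way that crossed the groups. The Spearman correlation across genes between a gene's deviation in a library and its GC content was -0.596, 0.595 and 0.393 in atractylon replicates 1 to 3 and -0.421, 0.176 and 0.020 in control replicates 1 to 3. Genes are not independent replicates, so no p-value was attached. Without atractylon replicate 2, with a trend nearly as wide as the widest, 190 genes (1.54%) had an unadjusted p below 0.05. Without atractylon replicate 1, which had the widest trend, 1319 genes (10.72%) had an unadjusted p below 0.05. The 2 treated libraries left in that fit had higher GC correlations than every control. Treatment and GC trend therefore cannot be told apart in it. In that fit 1 gene passed the threshold and was lower, the zinc finger gene ZNF516 (log2 fold change -2.03 ± 0.18, SE, edgeR adjusted p = 0.000556), and 4 lists were higher and 2 lower. None of these lists passed with an estimated correlation, at adjusted p of 0.950 or above.

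**Figure D3:**
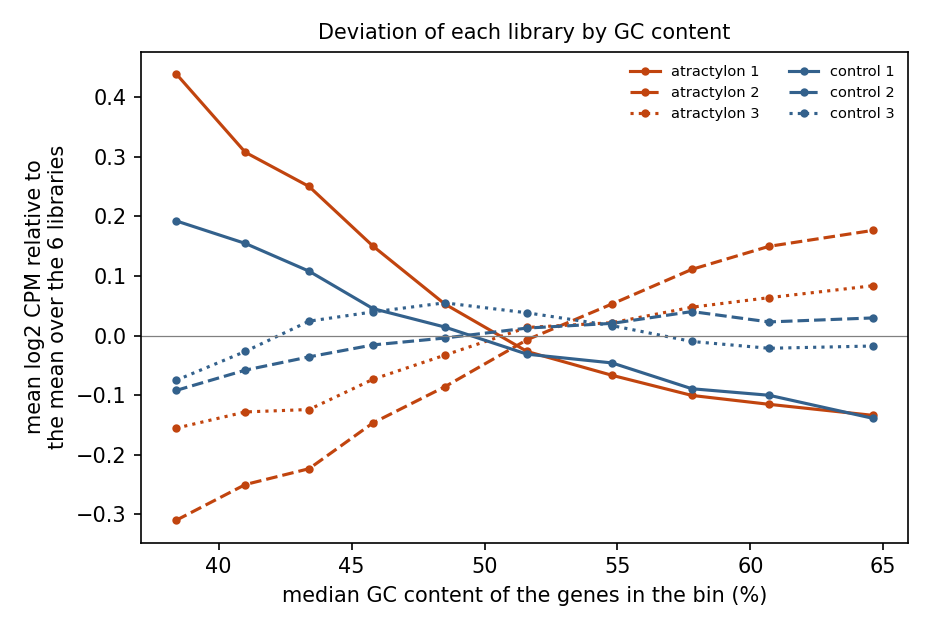
Mean log2 CPM of the genes in 10 bins of GC content, relative to the mean over the 6 libraries (vertical axis), against the median GC content of the bin in percent (horizontal axis). Each line is a library, coloured by group and drawn by replicate number. Atractylon replicate 1 falls from 0.439 to -0.134 across the bins and atractylon replicate 2 goes from -0.310 to 0.176, while control replicate 1 falls from 0.193 to -0.139.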

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

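The alternatives that remove GC or length trends, use DESeq2, use limma on log2 CPM, keep unmatched transcripts or leave out the first replicate of both groups were chosen after seeing the data. In 24 of 26 refits 0 genes passed the threshold, and no lncRNA passed in any of the 26. The share of genes with an unadjusted p below 0.05 ranged from 0.83% to 10.72%. Without atractylon replicate 1, 1 gene was lower (ZNF516), and over the replicates left out in turn the count of lower genes ranged from 0 to 1. With the first replicate of both groups left out, 1 gene was higher (FAAP100, log2 fold change 0.88 ± 0.10, SE, edgeR adjusted p = 0.0311) and 1 was lower (ZNF516, -1.91 ± 0.16, adjusted p = 0.00245), with 5 lists higher and 2 lower. None of these lists passed with an estimated correlation (camera adjusted p = 0.855 for each). Here, and without atractylon replicate 1, the treated libraries kept had higher GC correlations than every control kept. So treatment and GC trend cannot be told apart in these 2 fits.

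The cholesterol and mitochondrial lists passed in 26 of 26 refits at the preset correlation, with means from 0.0866 to 0.192 and from -0.316 to -0.155. With an estimated correlation and with fry, 0 lists were higher and 0 lower: the cholesterol list, at a mean of 0.143, had adjusted p of 0.0882 and 0.443, and the mitochondrial list, at -0.230, of 0.731 and 0.677. More lists passed elsewhere and the cause was not tested: 2 higher with no filter, and 3 higher and 2 lower with a filter at FPKM 1. In the DESeq2 refit 2 were higher and 2 lower. Its list test was camera on log2 CPM without trimmed-mean scaling, and no DESeq2 statistic entered it. In each fit on log2 FPKM 2 were higher (limma as first planned, pseudocounts 1 and 0.1, TPM, quantile scaling, no trend, robust). There were 3 higher and 2 lower with the GC trend or both trends removed, and 2 and 2 with the length trend removed. Leaving out each replicate in turn gave 1 to 4 lists higher and 2 to 4 lower: 4 and 2 without atractylon replicate 1, 1 and 3 without 2 and 2 and 2 without 3, then 3 and 2 without control replicate 1, 2 and 3 without 2 and 3 and 4 without 3. None of the lists that passed in a refit passed in any refit with an estimated correlation. In draws with independent genes, that test called 0 of 20 shifts of the cholesterol list and 0 of 20 of the mitochondrial list. Its failures alone therefore do not argue against a list.

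Same-numbered libraries correlated at 0.132, 0.176 and 0.011 in their deviations from the group means, and 2 of the 3 treated libraries correlated best with their own number. The third fell below 0.1, the correlation set as needed, so the numbers were not taken as pairs in the main test. A batch shared by same-numbered libraries stays open. The replicate block lowered the common dispersion from 0.0269 to 0.0182 and raised the genes with an unadjusted p below 0.05 from 196 to 297. Both first replicates had negative GC trends. With the block, 0 genes passed and 2 lists were higher and 2 lower. None of these lists passed with an estimated correlation (camera adjusted p of at least 0.676).

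No gene that the rule took passed in any of the 26 refits, and 904 of 909 values kept their sign. The others were CCDC183 and DSG2 without atractylon replicate 1, TMPO without atractylon replicate 2 and without control replicate 1 (0.0162), and DSG2 (-0.293) with the first replicate of both groups left out. Over the replicates left out in turn, log2 fold changes ranged from -0.426 to 0.0187 for CCDC183, from -0.205 to 0.391 for DSG2 and from -0.171 to 0.0799 for TMPO. The kept signs are no test of stability. Genes taken for their smallest p had groups that did not overlap, so leaving out a library could hardly reverse them. Refits that changed only the moderation left the fold changes as they were.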

Other observations

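The genes of fat synthesis were described above only as a list, and its members had fold changes of both signs. Of 24 tested members 5 had higher values and 2 had lower values in all 3 treated libraries than in any control, where chance gives 10% for both together. The higher ones were ACLY, which makes cytosolic acetyl-CoA, at 752 ± 42.9 against 596 ± 31.1 CPM, the fatty acid synthase FASN at 4460 ± 425 against 3300 ± 607 CPM, and the regulator SREBF1 at 97.5 ± 15.5 against 79.95 ± 3.67 CPM. The desaturases SCD and FADS2 were at 1810 ± 134 against 1470 ± 191 CPM and at 290 ± 32.3 against 224 ± 10.2 CPM. The lower ones were the lipid droplet protein PLIN2, at 216 ± 5.54 against 251 ± 17.7 CPM, and the acyl-CoA synthetase ACSL5, at 100.4 ± 2.46 against 111 ± 6.49 CPM. ELOVL6, FADS1 and ACACB overlapped between the groups, with log2 fold changes of -0.17 ± 0.38 (SE), 0.05 ± 0.10 and 0.04 ± 0.19. None passed the threshold (edgeR adjusted p = 0.9999 for each, n = 3 per group), the list did not pass (adjusted p = 0.0741, or 0.731 with an estimated correlation), and these genes were chosen after their values were seen. With GC and length trends removed, the standard errors of ACLY and FADS2 fell to 0.059 and 0.058, at log2 fold changes of 0.33 and 0.32, and their adjusted p became 0.549 for both. The log2 fold change of SCD went from 0.307 to 0.361, that of FASN from 0.434 to 0.365 and that of SREBF1 from 0.286 to 0.205. The list mean went from 0.0742 to 0.0599 (camera adjusted p = 0.00998, or 0.355 with an estimated correlation).

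Transcripts were also tested as features of their own. Of 39882 transcripts tested by edgeR, 0 were higher and 0 lower, with 927 at an unadjusted p below 0.05. Of 137 lncRNA transcripts, 0 were higher and 0 lower, with 1 at an unadjusted p below 0.05.

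Of the tests that follow, those of library depth on the 2 lists and of the most abundant genes were written before their results were seen, and all others after. The criterion for shared variation was the third tried, chosen after the outcomes of the first 2 were seen: both of those favoured shared variation for the mitochondrial list, and for the cholesterol list the first left it open and the second argued against it. The criteria for depth were also made stricter after their outcomes were seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share below 0.05. The real split had 0 genes and 0 lncRNAs past the threshold, so all 10 splits gave as many by construction (highest other 2 and 0), which tests nothing, and 7 splits gave as many lists (2, highest other 6). The split of atractylon replicate 1 with control replicates 1 and 3 from the rest put 2427 genes at an unadjusted p below 0.05, against 196 in the real split, which points to a structure of the samples other than treatment. With GC and length trends removed the same splits had 917 and 418.

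The first pattern weighed was the higher cholesterol list. GC and length trends as the whole cause were argued against, since their removal left a mean log2 fold change of 0.130 (camera adjusted p = 2.24e-12, or 0.355 with an estimated correlation) with all 3 treated libraries above every control. Library depth stays open: thinning every library to 5336192 counts left a mean of 0.138 (camera adjusted p = 1.665e-07). This met the condition set beforehand for arguing against depth. However, thinning hardly moves the CPM of abundant genes, so it decides nothing. Shared variation of the members stays open too. Their estimated correlation was -0.0075, and held fixed at 0 in place of this negative value it kept the call (adjusted p = 2.15e-10), but its 95% interval on 4 residual degrees of freedom, -0.026 to 0.197, held the correlation of 0.155 at which the call ends. In size, 2 of the 10 splits gave a mean of 0.143, equal at the digits printed, and 0 other splits gave a larger one. Besides the real split this was atractylon replicates 1 and 2 with control replicate 1 against the rest. Its camera adjusted p at the preset correlation was 0.00306, against 2.13e-08 in the real split. With the trends removed, 0 other splits gave a larger mean (0.130, highest other 0.102). There are too few splits to judge chance. A treatment effect on sterol genes may underlie the shift and remains a hypothesis.

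The second pattern was the lower mitochondrial list. Depth stays open for the same reason, with a mean of -0.229 after thinning (camera adjusted p = 4.703e-08), which also met the condition set beforehand. Members that vary together between libraries are a candidate explanation that stays open: the estimated correlation of 0.524, held fixed, ended the call (adjusted p = 0.115), but its 95% interval, 0.135 to 1, held the 0.375 at which the call ends. GC and length trends cannot be told apart from treatment here: with them removed the mean was -0.181, but the difference between groups of library means, -0.17 ± 0.18 (SE), lay within its own error. In size, 1 of the 10 splits, the real one, gave a mean as large (-0.230, highest other -0.218), too few splits to judge chance. Camera's p at the preset correlation did not set the real split apart. Atractylon replicates 1 and 2 with control replicate 2 against the rest gave a camera adjusted p of 1.56e-10, against 1.12e-09. With the trends removed, 4 other splits gave a larger mean (up to -0.311), and 1 treated library lay below every control. The largest of these had a camera adjusted p of 5.02e-15, against 0.000303 for the real split.

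The third pattern was the shortage of small p-values. Removing GC and length trends lowered the common dispersion 2.83-fold, from 0.0269 to 0.00951, and raised the genes with an unadjusted p below 0.05 from 196 to 418 of 12302 (3.40%), consistent with trends that crossed the groups and widened the spread within them. Depth as the source of the GC trends stays open: the negative trends lay in the shallowest library and in the second deepest, and trend and depth had a Spearman correlation of -0.086 (exact permutation p = 0.919) and a Pearson correlation of 0.128 (exact permutation p = 0.818; -0.829 without the 2 libraries farthest from the median depth). Low counts were argued against, since 1.07% of the 3076 most abundant genes, with 65.9 CPM or more, had an unadjusted p below 0.05. No gene passed after the removal, and no biological explanation was tested.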
